A study of Caenorhabditis elegans with 6 samples.

How the data were processed

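Small RNA libraries from L3 larvae were analysed from the deposited count tables, 1 table per library and 6 libraries in all. Per the labels' protocols, total small RNA was isolated from whole larvae, and NRDE-3-bound RNA was recovered from lysates with an antibody against the FLAG tag of the NRDE-3 fusion protein and released with FLAG peptide. Both kinds of RNA were treated with phosphatase and then with polynucleotide kinase and 1 mM ATP, which lets siRNAs with a triphosphate end be ligated, and RNA of 17 to 30 nt was gel-purified, ligated to adaptors and sequenced on an Illumina HiSeq instrument. The labels give 15 °C as the temperature of every sample, while the growth protocol gives 20 °C for maintenance before the experiment. Both hold for all groups alike. Groups follow the sample titles, and the growth, library method and stage do not differ between groups per the labels.

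Per the file headers, each table holds a raw count of reads on the strand of the feature and a raw count on the opposite strand, with the feature's class and description. The authors aligned reads with Bowtie2 per the submitters' processing notes. Its version and settings, the rule for reads that match several places, the genome build and the annotation release are not given in the sources used here. Because no size of each read is given in the tables, siRNAs cannot be separated from other antisense fragments by length. The tables list 56377 transcript-level features. These were summed to 45510 genes by the gene identifiers in the files, of which 43622 were found in the reference table of gene names. The tables held 5 blank count cells, read as 0, and 3 features that name no gene were left out (at most 122 counts per library). No coordinates are given in the tables, and none were added. Total counts ranged from 9122066 to 10755494 per library, so that 1 count was 0.0930 to 0.110 counts per 1000000 counts (CPM), and a count of 0 allowed a share of up to 2.79e-05% to 3.29e-05% (3 counts).

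Before the data were examined, the groups, tests, gene lists, the rule for named genes and a set of alternatives were fixed. The main measure was the antisense count. For rRNA and for each class of gene the share of all counts was computed with an exact 95% Clopper-Pearson interval. Ratios of shares between 2 libraries have the exact conditional interval of the 2 counts. Gene by gene, log2((CPM + 1)/(CPM + 1)) was computed for genes with at least 50 antisense counts over the 2 libraries compared, and genes at 1 or more or at −1 or less were counted as at least 2-fold higher or lower. This rule describes the libraries and is not a test. No p-value was computed: each group has 1 library, and a fit of the fraction across genotypes was not run. For each of 25 gene lists with at least 3 tested members, the median log2 ratio was placed as a percentile among 10000 random lists matched on mean expression in 20 bins. Random lists draw single genes. For lists of gene copies that may share reads, the percentile may thus overstate how many independent genes moved. The lists were the 4 nuclear rRNAs, mitochondrial rRNA, microRNA, 21U-RNA, tRNA, spliced leader RNA, snoRNA, snRNA, ribosomal protein, histone, collagen, sperm, intestinal, muscle, neuronal, germline, ERGO-1 target, WAGO target, small RNA pathway, rRNA processing, mutated or transgene loci, and stress genes. Mitochondrial rRNA had no gene tested, with at most 14 antisense counts per library. The list of mutated or transgene loci had medians of −1.32 and −0.49 in the total libraries of susi-2 and susi-3 and 1.08 in the IP of susi-2. Genes named in the text are the nuclear rRNA genes, the mutated or transgene loci, the 2 members of a described list with the highest mean CPM, and the 6 highest and 6 lowest log2 ratios with at least 200 counts outside the structural and small RNA classes. The same rule gave the genes of the IP-to-total comparisons, of which cup-16, clec-72 and linc-133 were picked for the text after their values were seen, as were the genes named for their sense fragments. Overlaps of the 2 mutants were set beside the product of independent lists and beside 100 simulated libraries that differ from the control by counting error only.

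The counts of rrn-4.2, rrn-4.3 and rrn-4.4 in the control total library showed under 1 in 10 counts on the annotated strand. The share planned for rRNA includes their antisense column and is given as written. The values per rRNA and the sum over the precursor genes leave them out, and a sum oriented by strand was added after the data were examined. The calculations were tested on simulated data for the real genes and library sizes, with 200 genes changed. These data carry counting error only, without variation between libraries or a shift of the bulk. They give no rate of false calls for the real libraries. The shares below are of changed genes with enough counts to be tested. For total small RNA of susi-2 (5363 genes tested), 98.3% of genes changed 4-fold and 28.6% of genes changed 2-fold passed the 2-fold rule. A 2-fold change lies on the threshold, and the added 1 CPM pulls ratios towards 0. None of the unchanged genes passed. For susi-3 (5457 genes) these shares were 98.3% and 32.3%, for the IP of susi-2 (4449 genes) 98.3% and 23.0%, and for the IP of susi-3 (2861 genes) 100% and 19.4%. The IPs had 1 and 2 unchanged genes passing.

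Alternatives covered edgeR's TMM scaling, DESeq2's median-of-ratios size factors, microRNA counts as the denominator, totals without structural RNA, other count minimums, pseudocounts and fold thresholds, and sense counts or both strands. Added after the data were examined were the strand-oriented sum, the share without the 3 oppositely annotated 5S copies, protein-coding genes only, sense counts for the gene lists, and counts without genes seen almost only in the IPs. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.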

Results

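Small RNAs were sequenced from Caenorhabditis elegans at the L3 larval stage in 6 libraries, 1 per group. The 3 genotypes were a control strain and the mutants susi-2(ust49) and susi-3(ust51), all in the eri-1(mg366) background and all carrying tagged NRDE-3, a nuclear Argonaute protein that binds secondary siRNAs antisense to their targets. The eri-1 mutation removes the endogenous siRNAs that NRDE-3 otherwise carries, which leaves the protein free to take up other siRNAs. Each genotype gave a total small RNA library and a library of the small RNAs recovered with NRDE-3 by immunoprecipitation (IP). Total counts per library were 10512324 (control), 10471072 (susi-2) and 9842186 (susi-3) for total small RNA, and 10755494, 9122066 and 9507040 for the IP libraries in the same order. Antisense counts made up 25.97%, 17.6% and 20.0% of the total libraries and 11.8%, 23.2% and 10.8% of the IP libraries. With 1 library per group no difference between genotypes has a replicate check. The 95% intervals below cover counting error only, and reads without molecular identifiers are not independent molecules.

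The series title names ribosomal siRNAs (risiRNAs), siRNAs antisense to ribosomal RNA, so the first question was how many counts lay antisense to the nuclear rRNA genes. These are rrn-1.1 and rrn-1.2 (18S), rrn-2.1 (5.8S) and rrn-3.1 (26S), processed from 1 precursor transcript, and the 16 copies of the 5S gene. Of the 5S copies, rrn-4.2, rrn-4.3 and rrn-4.4 carried their abundant fragments in the antisense column. From these counts alone, their annotated strand was read as opposite to that of the other 13. Counts antisense to 5S therefore come from the 13-copy set unless stated otherwise. Most copies had near-equal sense counts, with 10 of the 13 within 10% of the median in the control total library. Of the others, rrn-4.15 had 2534 sense counts and rrn-4.16 had 4. How reads shared by copies were divided is not given, so 5S is given as a sum. Sense fragments of rRNA were the largest class in each IP library and 29.0% of the control total library.

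The mutated loci came first. From background knowledge, susi-2 is rrp-8 (T07A9.8), which encodes an rRNA methyltransferase of the large subunit, and susi-3 is riok-1 (M01B12.5), which encodes a kinase of small subunit maturation. Sense counts on rrp-8 were 30 in the control total library, 10 in susi-2 and 36 in susi-3, a ratio of 0.335 (0.146 to 0.703) for susi-2. In the IP libraries they were 106, 31 and 51, a ratio of 0.345 (0.223 to 0.519) for susi-2 and 0.544 (0.382 to 0.767) for susi-3. Sense counts on riok-1 were 94, 138 and 89 in the total libraries and 427, 344 and 366 in the IP libraries, so the susi-3 ratios were 1.01 (0.748 to 1.37) and 0.970 (0.841 to 1.12). The labels do not give the lesions, so these counts are no firm check of the genotypes. Sense counts on eri-1 (T07A9.5), mutated in every strain, were at most 47 per library. The nrde-3 gene (R04A9.2) had 442, 1146 and 571 sense counts in the total libraries and 55056, 35725 and 40741 in the IP libraries, so the IP share was 122-fold (111 to 134), 35.8-fold (33.7 to 37.98) and 73.9-fold (68.0 to 80.4) that of the total library of the same genotype. Transcripts of unc-119 (M142.1), a gene used as a rescue marker in worm transgenes, had 61, 36 and 65 sense counts in the total libraries and 351, 211 and 166 in the IP libraries.

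The comparison of total small RNA in susi-2 with the control asks whether siRNAs against rRNA accumulate when rrp-8 is mutated. Antisense counts on the 26S gene were 1214 in susi-2 and 220 in the control, 5.54-fold higher as a share (4.79 to 6.42). The share was 3.97-fold higher for 5.8S (2.83 to 5.68), 2.72-fold for 5S (2.33 to 3.18) and 2.62-fold for 18S (2.06 to 3.34). The precursor genes together (18S, 5.8S and 26S) gave 4.57-fold (4.07 to 5.13), while their sense fragments differed by a factor of 1.11 (1.11 to 1.12). By rRNA, the sense ratios were 1.005 for 26S, 1.42 for 18S, 1.22 for 5.8S and 1.89 for 5S, so that the antisense percent of 5S counts rose only from 0.282 to 0.405. These antisense counts were rare: 26S made up 0.0116% of the library (0.0110 to 0.0123) against 0.00209% in the control (0.00183 to 0.00239). With all 16 copies of 5S in the antisense column as written, the ratio was 2.03 (2.00 to 2.06).

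Among 5362 genes with enough antisense counts, 211 were at least 2-fold higher in total small RNA of susi-2 and 1339 at least 2-fold lower, with a median log2 ratio of −0.60. Scaling by TMM, which sets the bulk of the genes to no change, placed its zero at −0.70 and gave 490 higher and 428 lower. The gene lists fixed beforehand are therefore read against the all-gene median. Antisense counts of snRNA genes had a median of 1.32, with 6 of 7 genes at least 2-fold higher and smy-1 at 3.11-fold. The snoRNA list had a median of 0.50 with 11 of 36 genes at least 2-fold higher and 5 lower, spliced leader RNAs 0.53, and ribosomal protein genes 0.30, with none of 36 at least 2-fold higher. These 4 lists and the histone genes (−0.22) lay in the top 2.5% of matched random lists. In the opposite direction, antisense counts on targets of the nuclear RNAi Argonautes (WAGO targets) had a median of −1.64, with 13 of 18 genes at least 2-fold lower. Of this list, bath-20 and bath-45 stood at ratios of 0.342 and 0.370. The ERGO-1 targets, genes that lose siRNAs when the eri-1 pathway fails, had a median of −2.50 over 6 of 25 genes. Of these, C18D4.6 was at a ratio of 0.0655 and R06C1.4 at 0.0640. The control carries the eri-1 mutation as well, and whether its counts on these genes were ERGO-1-dependent siRNAs was not tested. Collagen genes had a median of −1.02 (7 of 14 at least 2-fold lower). These 3 lists lay below the 2.5th percentile. Germline genes (−0.60), the small RNA pathway (−0.59) and rRNA processing genes (−0.57) moved with the bulk. The neuronal list had a median of −1.25, the sperm list −0.98 and the stress list −0.44, all between these limits.

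The highest single genes were C18H2.4 (515 counts against 11, 47.003-fold, 26.05 to 94.7), arrd-17, an arrestin domain gene (20.1-fold), fbxa-171, an F-box gene (20.2-fold), cfap-36 (14.4-fold), Y57G7A.2 (7.92-fold) and rpr-1, the RNA of ribonuclease P (6.21-fold). The lowest held 3 transposon features of 1 clone, F57G4.7 (32 counts against 4510, ratio 0.00712), F57G4.9 (14 against 1666) and F57G4.6 (5 against 1032). They also held saeg-2 (57 against 7073), C08F11.7 (10 against 1710) and lido-18 (42 against 4393). As classes, antisense counts on transposons had a ratio of 0.401 (0.398 to 0.404) and on protein-coding genes 0.505 (0.504 to 0.507), and 21U-RNAs, the germline piRNAs, had a sense ratio of 0.327 (0.323 to 0.330). MicroRNAs had a ratio of 0.944.

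The same comparison for susi-3 asks about riok-1. Antisense counts were 441 on 18S against 97, 4.86-fold higher (3.89 to 6.11), and 413 on 26S against 220, 2.01-fold higher (1.70 to 2.37). The order of the 2 large rRNAs was thus the reverse of that in susi-2: 18S made up 51.6% of 18S and 26S antisense counts in susi-3 (48.2 to 55.04), 30.6% in the control (25.6 to 35.99) and 17.2% in susi-2 (15.3 to 19.3). The 5.8S share was 2.31-fold higher (1.59 to 3.40), the 5S share 2.35-fold (2.00 to 2.76) and the precursor sum 2.81-fold (2.49 to 3.18), with precursor sense fragments at 0.954. The sense ratios were 0.882 for 26S, 1.14 for 18S, 1.24 for 5.8S and 1.72 for 5S, and the antisense percent of 5S counts was 0.385 against 0.282 in the control. As written, with all copies of 5S, the ratio was 1.86 (1.83 to 1.89).

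**Figure D1:**
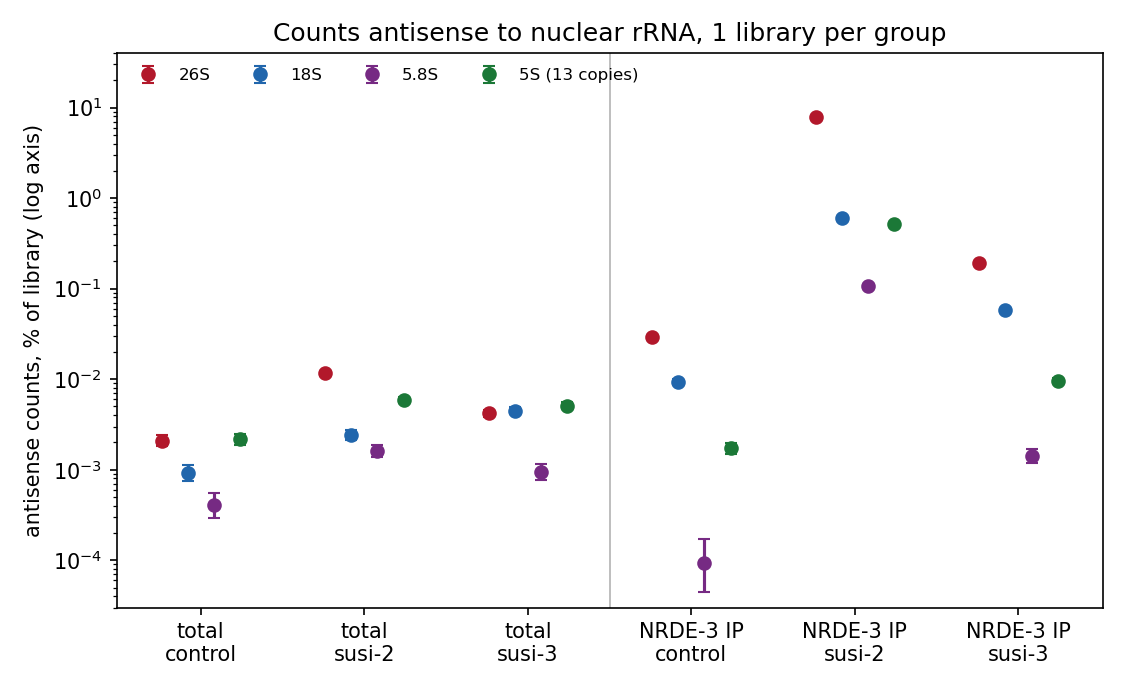
Counts antisense to 26S, 18S, 5.8S and 5S rRNA (13 copies) as a percent of all counts of the library, on a log axis, in the 6 libraries (1 per group). Bars are exact 95% binomial intervals. The 26S share runs from 0.00209% in the control total library to 7.86% in the susi-2 IP library.

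Of 5460 genes, 299 were at least 2-fold higher in total small RNA of susi-3 and 1010 at least 2-fold lower (median log2 ratio −0.56), or 600 and 212 with TMM, whose zero lay at −0.63. Antisense counts of structural RNA genes stood out. Copies of these genes and of histone genes may share reads, so the genes counted here and in the IPs may not be independent. All 40 snRNA genes tested were at least 2-fold higher (median 2.08), with smy-1 at 16.2-fold (773 counts against 51) and smy-8 at 4.33-fold. Spliced leader RNAs, which are trans-spliced to mRNAs, had 13 of 14 at least 2-fold higher (median 1.84, sls-2.8 at 3.96-fold), and snoRNAs 23 of 41 (median 1.45), while the snoRNA with the most counts, K07C10.2, had a ratio of 0.362. Histone genes had 33 of 62 at least 2-fold higher (median 1.05). The abundant his-24, a linker histone gene, was at 0.577, and his-15 at 3.46-fold. Ribosomal protein genes had a median of 0.17, in the top 2.5% like the lists before them. The rRNA processing list had a median of −0.77 and lay below the 2.5th percentile, with toe-1 at a ratio of 0.417. The WAGO targets (−0.74), ERGO-1 targets (−0.42), germline genes (−0.73), collagens (−0.49), the small RNA pathway (−0.67), the neuronal list (−0.52), the sperm list (−0.68) and the stress list (−0.49) lay between these limits.

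The highest single genes in susi-3 were the ncRNA C18C4.17 (24.4-fold, 14.6 to 44.1), arrd-17 (23.7-fold), shc-2 (21.03-fold), R102.4 (11.2-fold), alg-1, a microRNA Argonaute gene (11.1-fold), and F23A7.4 (8.72-fold). With both strands counted together C18C4.17 turned to a log2 ratio of −1.54. The lowest were C08F11.7 (48 counts against 1710), droe-4 (13 against 400), nhr-229, a nuclear hormone receptor gene (19 against 486), lnp-1 (24 against 393), Y102A5C.36 (211 against 2340) and the collagen gene col-60 with 0 counts against 267, at least 83.3-fold lower when 0 is taken at 3 counts. Transposon antisense counts had a ratio of 0.656 (0.651 to 0.660), protein-coding genes 0.676 (0.674 to 0.678), and 21U-RNAs 0.460 (0.455 to 0.464), while snRNA antisense counts were 9.47-fold higher (8.65 to 10.4) and their sense fragments were at 0.462 (0.453 to 0.471).

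**Figure D2:**
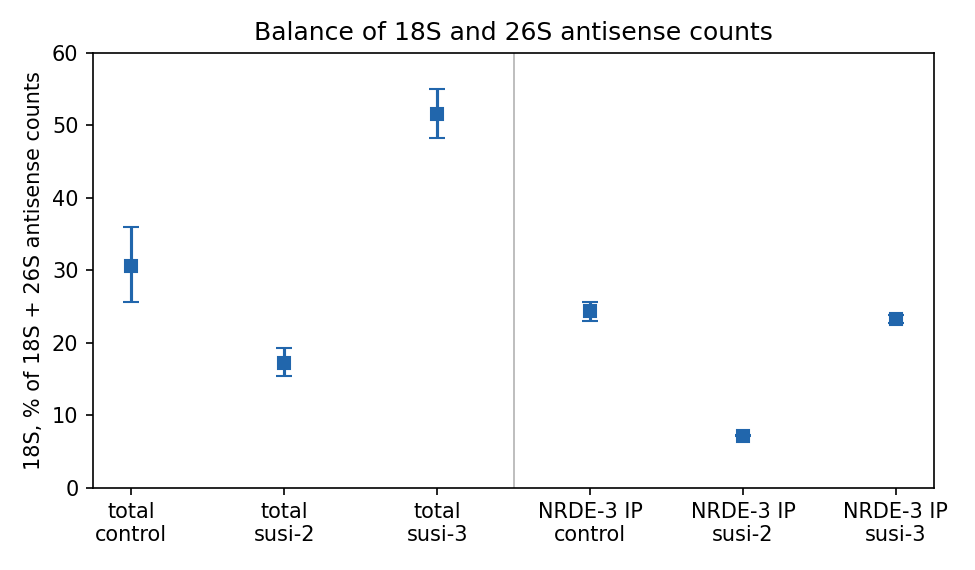
Percent of 18S among 18S and 26S antisense counts in each library, with exact 95% binomial intervals and 1 library per group. The percent was 30.6 in the control total library, 17.2 in susi-2 and 51.6 in susi-3, and 24.3, 7.17 and 23.3 in the IP libraries.

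The IP libraries ask which small RNAs were recovered with NRDE-3 in each mutant. In susi-2, antisense counts on 26S were 717187 against 3147 in the control, 7.86% of the library (7.84 to 7.88) against 0.0293% (0.0282 to 0.0303), or 269-fold higher (259 to 278). The 18S share was 64.5-fold higher (60.6 to 68.7) with 55364 counts against 1012, the 5S share 303-fold (262 to 352) with 47539 against 185, and the 5.8S share 1164-fold (633 to 2429) with 9874 against 10. The precursor sum was 221-fold higher (215 to 228), and its sense fragments were at 0.907. Of all counts on the 26S gene, 16.6% were antisense in this library and 0.0686% in the control. On 5S antisense counts outnumbered sense counts, at 64.3% (64.0 to 64.6) against 0.489%. Over the 4 rRNAs, 26S made up 86.4% of antisense counts in susi-2 and 72.3% in the control. As written, with all copies of 5S, the ratio was 59.6 (58.7 to 60.5).

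Antisense counts on other genes were also spread more widely in this library. Of 4436 genes, 2031 were at least 2-fold higher and 237 at least 2-fold lower (median log2 ratio 0.92), or 719 and 787 with TMM, whose zero lay at 1.09. Against that median the structural RNAs were high. All 16 snRNA genes were at least 2-fold higher (median 2.81, sup-6 at 12.4-fold), with 48 of 52 snoRNAs (2.43), 7 of 8 spliced leader RNAs (2.03) and 24 of 28 tRNA genes (1.83). The snoRNA exceptions included K07C10.2, at a ratio of 0.747. Ribosomal protein genes had 55 of 61 at least 2-fold higher (median 1.79, rpl-43 at 7.69-fold), and rRNA processing genes 22 of 30 (1.499), with ncl-1, a regulator of nucleolar size, at 6.01-fold. These lists lay in the top 2.5% of random lists. The WAGO targets lay below the 2.5th percentile, with a median of −0.24 and 6 of 15 genes at least 2-fold lower. Between these limits were histones (0.75), germline genes (0.97), collagens (0.78), the small RNA pathway (1.06), muscle genes (0.98), intestinal genes (0.59), the neuronal list (0.98), the stress list (1.30), ERGO-1 targets (1.499) and microRNA genes (1.33). In the small RNA pathway list alg-1 had 9644 counts against 388, 29.3-fold higher. MicroRNAs themselves had a sense ratio of 0.487 and protein-coding antisense counts a ratio of 1.74.

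The highest single genes in the susi-2 IP were F19B10.13 (223-fold, 127 to 432), F32B5.2 (212-fold), Y75B8A.28 (133-fold), ZK632.4 (87.6-fold), lipl-4, a lysosomal lipase gene (643 counts against 0, at least 253-fold with 0 taken at 3 counts), and gst-33, a glutathione transferase gene (482 against 0, at least 189-fold in the same way). The lowest were C25G6.4 (32 against 6412), irld-51 (34 against 5739), Y56A3A.6 (72 against 10601), T22F7.3 (68 against 6238), hasp-1, a haspin kinase gene (ratio 0.0185), and K08E7.5 (182 against 10244).

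In the susi-3 IP, antisense counts on 26S were 18018 against 3147, 6.48-fold higher (6.24 to 6.73), and on 18S 5473 against 1012, 6.12-fold higher (5.72 to 6.55). The 5S share was 5.57-fold higher (4.75 to 6.56), the 5.8S share 15.3-fold (8.05 to 32.6) and the precursor sum 6.41-fold (6.20 to 6.63), with its sense fragments at 1.13. Antisense counts made up 0.376% of the counts on 26S. The percent of 18S among 18S and 26S was 23.3 (22.8 to 23.8) against 24.3 in the control (23.04 to 25.7), so the higher weight of 18S seen in total small RNA was not seen here. As written, with all copies of 5S, the ratio was 2.32 (2.28 to 2.37).

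Of 2823 genes, 332 were at least 2-fold higher in the susi-3 IP and 648 at least 2-fold lower (median log2 ratio −0.37), or 447 and 296 with TMM, whose zero lay at −0.46. The 5S list (1.89) and the ribosomal protein genes (0.20, 1 of 25 at least 2-fold higher) lay in the top 2.5% of random lists, and the WAGO targets below the 2.5th percentile, with a median of −1.49 and 11 of 13 genes at least 2-fold lower. The structural RNA lists that were high in susi-2 were at −0.01 (snoRNA) and −0.24 (tRNA) here. Between these limits were also histones (−0.72), germline genes (−0.59), the small RNA pathway (−0.71), ERGO-1 targets (−0.99), rRNA processing (−0.28), collagens (−0.57), the neuronal list (−0.67), muscle genes (−0.14), intestinal genes (−0.06), the stress list (−0.17) and microRNA genes (−0.22). The highest single genes were F32B5.2 (360-fold, 201 to 722), Y75B8A.28 (195-fold), ZK632.4 (135-fold), lipl-4 (at least 300.2-fold with 0 taken at 3 counts), gst-33 (at least 288-fold) and nurf-1, a chromatin remodelling gene (75.5-fold). The 6 lowest were those of the susi-2 IP, C25G6.4 having 23 counts against 6412. MicroRNAs had a sense ratio of 0.560 and 21U-RNAs 0.412.

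**Figure D3:**
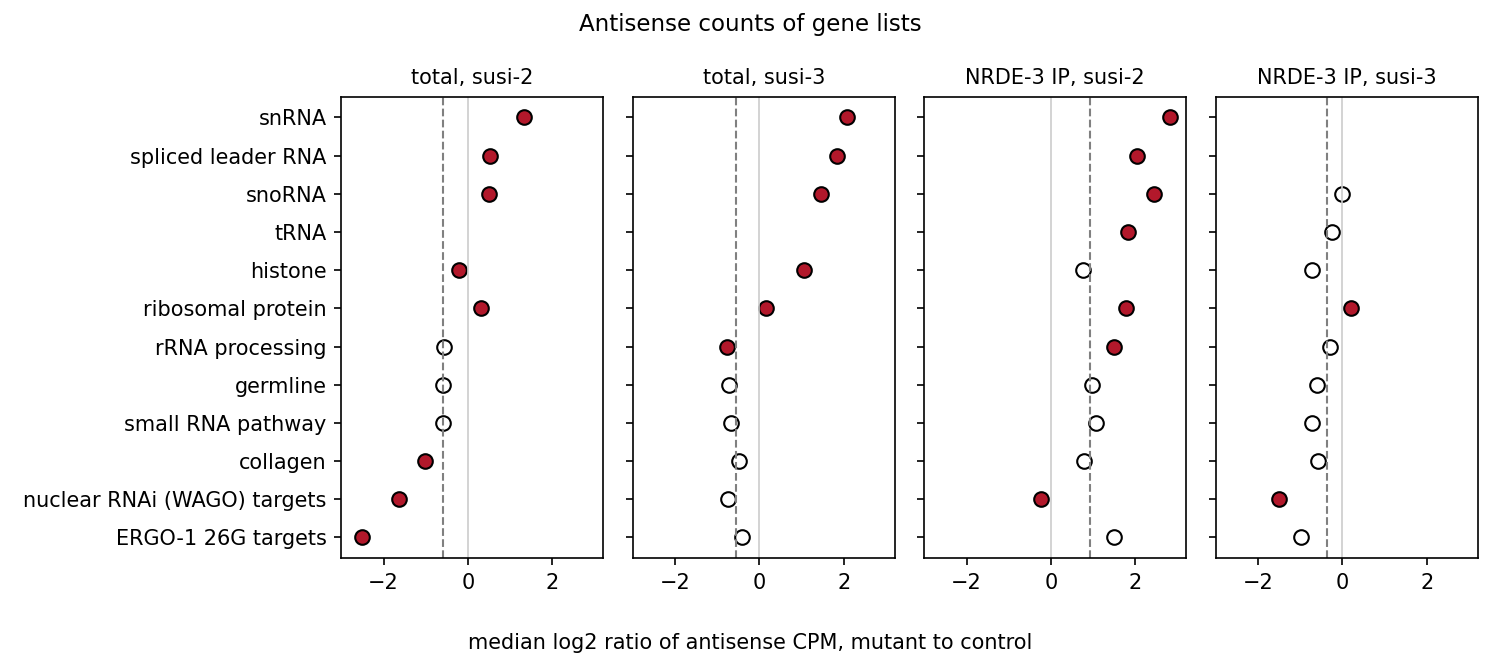
Median log2 ratio of antisense counts per 1000000 counts, mutant to control, for 12 gene lists in the 4 comparisons with 1 library per group. Filled points lie in the top or bottom 2.5% of matched random lists, and the dashed line is the median of all genes tested (−0.60, −0.56, 0.92 and −0.37 from left to right). Lists with fewer than 3 tested genes have no point.

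The IP libraries were then set against the total library of the same genotype, to ask which RNAs were enriched with NRDE-3. No library came from an IP without tagged NRDE-3. These ratios therefore cannot part RNA bound by NRDE-3 from RNA carried over in the pull-down. The share antisense to 26S was 13.98-fold higher in the IP than in total small RNA in the control (12.2 to 16.1), 678-fold in susi-2 (641 to 718) and 45.2-fold in susi-3 (41.0 to 49.9). For 18S these ratios were 10.2, 251 and 12.8, for 5.8S 0.227 (0.102 to 0.459), 66.7 and 1.503, and for 5S 0.797 (0.652 to 0.972), 88.9 and 1.89. The precursor sum gave 11.3-fold (10.2 to 12.6), 549-fold (523 to 576) and 25.8-fold (24.2 to 27.6). As written, with all copies of 5S, the ratios were 0.578, 17.0 and 0.721, so the direction in the control and susi-3 depended on the 3 oppositely annotated copies. Across genes, 627 were at least 2-fold higher and 3739 lower in the control IP (of 5281), 1752 and 1767 in susi-2 (of 5574) and 632 and 2777 in susi-3 (of 4219). Histone genes were high in each IP, with medians of 2.16, 3.04 and 0.47, and so were ribosomal protein genes against the bulk (−0.20, 1.45 and −0.01). Spliced leader RNAs were low in the control (−2.68) and susi-3 (−3.17), and all 40 snRNA genes were at least 2-fold lower in the susi-3 IP (−2.62). In susi-2 the snRNA list went the other way, with 14 of 20 genes at least 2-fold higher and 3 lower (2.13), and all 26 tRNA genes were at least 2-fold higher (3.205). The WAGO targets had medians of −4.11, −2.64 and −4.61, where all genes tested had −1.82, −0.09 and −1.72. Their percentiles of 13.22, 2.625 and 4.81 among random lists lay between the limits. Single genes with many counts in the IP and few in total were cup-16, with 14459, 7871 and 10702 antisense counts in the IPs against 0 in each total library, and clec-72, a C-type lectin gene, at 555-fold in susi-2 and 1340-fold in susi-3. The noncoding RNA linc-133 had 9130 counts against 1 in susi-2 (10480-fold, 1881 to 413990).

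Last, the mutants were compared with each other through the genes they shared. In total small RNA, 88 genes were at least 2-fold higher in both mutants, from 168 in susi-2 and 209 in susi-3 of 5108 genes tested in both, where independent lists would share 6.87. At least 2-fold lower in both were 430 genes, from 1336 and 1005, where independent lists would share 263. In the IPs 296 of the 305 genes higher in susi-3 were also higher in susi-2 (1008 genes, of 2775 tested), against 111 for independent lists, and 215 were lower in both (230 and 646), against 53.5. These shares depend on the scaling: with DESeq2 size factors 233 were higher in both (of 335 and 418) and 250 lower in both (of 763 and 289). Simulated unchanged libraries against the same control shared at most 1 gene, but they carry counting error only and say nothing about variation between worm samples. Part of each excess may come from the control, since both mutants were compared with 1 control library per fraction.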

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

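Of the tests in this part, those on library yield from other enriched genes and on the likeness of the 2 mutant IPs were set before their values were seen, and the others only after. The rules looked for classes of RNA whose ratios went opposite ways in 2 comparisons and for signal in the sense counts, which the comparisons above do not use. No difference between comparisons was tested, since each group has 1 library.

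Antisense counts on lincRNA genes had ratios of 0.319 (susi-2) and 0.639 (susi-3) in total small RNA but 5.81 and 6.62 in the IPs. The gene linc-133, with 311, 9130 and 15015 antisense counts in the IPs of control, susi-2 and susi-3, makes up most of this. Without it the IP ratios were 2.24 (2.14 to 2.36) and 0.667 (0.625 to 0.711), so in susi-3 the IP and total libraries did not go opposite ways. Antisense counts on protein-coding genes in susi-2 had a ratio of 0.505 in total small RNA and 1.74 in the IP. Antisense counts on snoRNA genes had a ratio of 3.09 in the IP of susi-2 and 0.664 in that of susi-3. In the sense counts, F31C3.13 and its neighbours in the rDNA were 454-fold higher in the susi-2 IP and 14.9-fold higher in the susi-3 IP. From their counts alone, these features were read as annotated against the strand of the rDNA, with a sense column antisense to rRNA. Sense fragments of mRNA in total small RNA had list medians (log2) of 1.44 for ribosomal protein genes, 1.24 for collagens and 1.03 for histones in susi-2, and of 1.11 for the list made for sperm (its highest members were nspc peptide genes), 1.10 for collagens and 1.02 for muscle genes in susi-3, each in the top 2.5% of random lists.

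The first pattern is the antisense rRNA in the susi-2 IP. At an equal rate of mis-stranding, fragments of degraded rRNA would keep the antisense percent of the precursor genes near that of the control. It was 207 times as high, which argues against this source at an equal rate. Whether the rate was equal was not tested. MicroRNA genes, with sense shares of 3.65% here and 7.49% in the control IP, had antisense shares of 0.0114% and 0.00878%. In the same order, snRNA genes had sense shares of 0.326% and 0.462% and antisense shares of 0.0265% and 0.00231%. For tRNA genes these were 0.126% and 0.237% sense, and 0.0787% and 0.0183% antisense. These antisense shares rose beside lower sense shares, though less than on rRNA. On ncRNA genes the antisense share was lower (1.18% against 1.66%). An equal rate can therefore not be assumed, and the value of 207 alone does not decide on this source. Also weighed were a better recovery of all NRDE-3-bound RNA, a loss of all other RNAs and a loss of those not bound by NRDE-3. Each was predicted to raise 18S and 26S antisense counts alike, but 26S rose 4.17 times as much as 18S (4.02 to 4.32). In total small RNA of susi-2, however, 26S was already 5.54-fold higher and 18S 2.62-fold. An unequal rise in the IP can thus come from the RNA put in, so this value cannot decide on these causes. The 155 genes enriched at least 4-fold in the susi-3 IP were compared between the susi-2 IP and the control IP. Beside an all-gene median of 0.92, their median log2 ratio was 1.89, with quartiles of 0.0473 and 3.98. The interval of this median (1.30 to 2.96) comes from resampling these genes, not from counting error. The 121 of them outside the set described next had the same median. By the limits set beforehand, the median of 1.89 counted against a better recovery of all NRDE-3-bound RNA, provided that these genes are NRDE-3 cargo. Whether they are was not tested. A better recovery or a loss of other RNAs stays open, beside an effect of the mutation.

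The second pattern is a set of genes with at least 500 counts in an IP and at most 10 in every total library, 47 genes by antisense counts and 28 by sense counts. If they were NRDE-3-bound siRNAs too rare to see in total RNA, hardly any protein-coding gene would meet the rule in the sense column. But 24 genes did beside 45 in the antisense column, 34.8% (23.7 to 47.2). This argues against that source for the sense counts only where the sense column is not itself antisense to another RNA. By its counts it is for F31C3.13, an rRNA feature also among the 28, and without coordinates the others cannot be checked. For the antisense counts the pooled enrichment in susi-2 was 784-fold (633 to 983) against 549-fold for the rDNA precursor, and the rule itself limits the counts in total RNA, so siRNAs, RNA carried over in the pull-down and material of another library cannot be told apart. Of the 47 antisense genes, 28 were alike in the mutants and at least 2-fold apart from the control, which a separate handling of the control IP could give as well as the genotypes, and the design does not part these. Several of the highest and lowest genes named for the IPs, such as C25G6.4 and F32B5.2, and linc-133 belong to this set.

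The third pattern is the lower 21U-RNA count in total small RNA of both mutants. Dilution by other RNAs would leave the ratio to microRNA counts near that of the control, and it was 0.346 (0.343 to 0.350) in susi-2 and 0.405 (0.401 to 0.409) in susi-3. Fewer germ cells would lower the sense mRNA fragments of germline genes, whose list lay at the 66.8th (susi-2) and the 89.0th (susi-3) percentile in total small RNA but below all random lists in the IPs (median log2 ratios −1.08 and −0.83), so this decides nothing and a smaller germline stays open. A difference in larval stage or culture between single samples stays open and was not tested, as does an effect of the mutations.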

How the results depend on the processing

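Each group has 1 library, so no difference between genotypes can be told from variation between animals, cultures or library preparations, and both mutants share 1 control per fraction. Mutant and control cannot be compared in pairs, since the labels give no replicate numbers. IP and total libraries pair by genotype, but a fit of the fraction across the 3 genotypes was not run. Reads are not sorted by length or first base, and reads from repeated genes are split by a rule that is not given. The strand-oriented sum, the share without the 3 oppositely annotated 5S copies, protein-coding genes only, sense counts for the gene lists, the counts without genes seen almost only in the IPs, and the enrichment ratios of the precursor genes and of the strand-oriented sum were chosen after the data were seen, and the others before. Unless a cause is named below, the cause of a shift was not tested.

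The rRNA ratio, planned with all copies of 5S, is given for total susi-2, total susi-3, IP susi-2 and IP susi-3 in this order. It was 4.57, 2.81, 221 and 6.41 for the precursor genes, 3.85, 2.63, 225 and 6.38 without the 3 oppositely annotated 5S copies, and 4.28, 2.76, 251 and 7.28 for the strand-oriented sum. Those 3 copies place sense fragments in the antisense column by construction, which lowers the ratio as planned. It was 2.15, 1.64, 122 and 4.14 per microRNA count, and 2.19, 1.80, 70.2 and 2.72 with structural RNA left out of the denominator. With sense counts it was 1.13, 0.974, 0.913 and 1.13, turning below 1 for total susi-3 and IP susi-2, and with both strands 1.14, 0.982, 1.08 and 1.13, turning below 1 for total susi-3.

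The IP-to-total ratio of rRNA for the control, susi-2 and susi-3 was 11.3, 549 and 25.8 for the precursor genes and 6.78, 397 and 17.9 for the strand-oriented sum, on the other side of 1 from the planned ratio in the control and susi-3. With structural RNA left out of the denominator it was 0.919, 29.4 and 1.39, which turned susi-3 above 1.

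Genes at least 2-fold higher and lower moved with the scaling. With TMM they were 490 and 428 (total susi-2), 600 and 212 (total susi-3), 719 and 787 (IP susi-2), and 296 lower in the IP of susi-3. With DESeq2 size factors they were 494 and 420, 605 and 201, 697 and 807, and 289 lower. Scaling by microRNA counts gave 182 and 899 in total susi-2, 181 and 975 in total susi-3, 3546 and 66 in the IP of susi-2, and 662 and 193 in the IP of susi-3. With structural RNA left out of the totals they were 236 and 1042 (total susi-2), 256 and 996 (total susi-3) and 2523 and 180 (IP susi-2). The excess of lower genes in total small RNA and of higher genes in the susi-2 IP was thus present under these 2 scalings. With TMM and DESeq2 size factors it was gone, and in total susi-3 it turned to an excess of higher genes. In the IP of susi-3 the excess of lower genes held with structural RNA left out (396 and 483) but turned to an excess of higher genes with TMM (447), DESeq2 (450) and microRNA scaling.

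Other settings are given as higher and lower for total susi-2, total susi-3, IP susi-2 and IP susi-3. A minimum of 200 counts gave 96 and 750, 119 and 427, 456 and 137, and 109 and 251. A pseudocount of 10.0 CPM gave 44 and 468, 65 and 154, 418 and 78, and 133 and 108. A threshold of 4-fold gave 26 and 185, 79 and 83, 584 and 52, and 189 and 93. Without a minimum 452 were higher in total susi-3, 3859 in the IP of susi-2 and 623 in that of susi-3. Protein-coding genes alone gave 99 higher in total susi-2, 139 in total susi-3 and 156 lower in the IP of susi-2. Sense counts gave 1314 and 717, 831 and 648, and 396 and 1473 for the first 3. Both strands gave 1063 and 821 higher in the total libraries, 938 and 905 in the IP of susi-2, and 1099 lower in that of susi-3. With both strands C18C4.17 turned to −1.54 in total susi-3.

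Lists in the top or bottom 2.5% of random lists fell to 5 in total susi-2, 4 in the IP of susi-2 and 1 in the IP of susi-3 with a minimum of 200 counts, and to 1, 4 and 1 for the IP-to-total comparisons of the control, susi-2 and susi-3. Collagens and histones in total susi-2, rRNA processing in total susi-3, tRNA and rRNA processing in the IP of susi-2 and 5S in that of susi-3 came to lie between the limits, and ribosomal protein genes kept too few members outside the IP of susi-2, as did snRNA outside total susi-3 and spliced leader RNA in the IP of susi-2. Of the IP-to-total lists, the neuronal list (control, susi-2), snRNA (susi-2, susi-3), 5S and spliced leader RNA (susi-3) also came to lie between them. With sense counts they were 15 in total susi-3 and 11 in the IP of susi-3. Genes shared by the mutants numbered 38 higher and 198 lower in total small RNA and 89 higher and 123 lower in the IPs with a minimum of 200 counts, and 258 higher and 92 lower in total small RNA and 233 higher and 250 lower in the IPs with DESeq2 size factors. That put 233 of the 418 higher and 250 of the 289 lower genes of the susi-3 IP among those of susi-2. Without the genes seen almost only in the IPs, 279 were shared higher and 204 lower, where independent lists would share 104 and 50.6, so that set does not carry the overlap.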

Other observations

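Sense fragments of mRNA gave a second view of the mutants, from values looked at only after the main results. The values are from total small RNA unless an IP is named. Whether RNA integrity or size selection differed between single samples was not tested. In total small RNA of susi-3, median log2 ratios were 1.11 (sperm list), 1.10 (collagens), 1.02 (muscle), 0.87 (neuronal list) and 0.99 (stress list). Each lay above all 10000 random lists. In the stress list, which mixes heat-shock genes with others, 15 of 31 genes were at least 2-fold higher. The chaperone genes hsp-70 (284 counts against 11, 27.6-fold, 15.2 to 55.9), hsp-16.41 (28.1-fold), hsp-16.2 (17.3-fold) and the hsp-16.1 copy T27E4.2 (25.5-fold) were among its highest members. Outside the list, the heat-inducible F44E5.4 (2688 against 160) was 17.9-fold higher and F44E5.5 17.8-fold. In susi-2 the same list had a median of 0.44, with 6 of 29 genes at least 2-fold higher. These included the pathogen response genes irg-5 (7.31-fold) and irg-4 (4.96-fold) and the chaperone genes hsp-4 (2.95-fold) and hsp-90 (2.32-fold). The others were the metallothionein genes mtl-2 (3.48-fold) and mtl-1 (18.4-fold, 5.98 to 92.0), the latter on only 55 counts against 3.

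In susi-2, fragments of 69 of 78 ribosomal protein mRNAs were at least 2-fold higher (median 1.44), with rpl-34 at 5.07-fold and rps-16 at 4.81-fold, against 1 of 78 in susi-3 (median 0.51). Over protein-coding genes the median was 0.51 in susi-2 and 0.31 in susi-3. The transporter gene pgp-8 was 141-fold higher in susi-2 (1120 against 8, 71.1 to 326), gst-24 41.9-fold and clec-52 11.3-fold. Collagen fragments were high in both, with dpy-13 at 4.48-fold in susi-2 and col-42 at 5.68-fold in susi-3, while bli-1 was at 0.0352 in susi-2. In susi-3, 13 of 19 genes of the list made for sperm were at least 2-fold higher, but its highest members were nspc peptide genes such as nspc-13 (6.19-fold), while spe-48 (1.51-fold) and spe-39 (0.922) were its lowest. In the same library 10 of 19 muscle genes were at least 2-fold higher, among them tni-3 (8.22-fold) and pat-10 (3.14-fold). In the IPs these lists did not all stay high. In the susi-3 IP the sperm list (−0.94) and ribosomal protein genes (−0.64) lay in the bottom 2.5% of random lists. Collagens (−0.40), muscle genes (−0.27) and the neuronal list (−0.20) lay between the limits, and the stress list (−0.05) in the top 2.5%. In the susi-2 IP ribosomal protein genes (−0.11) lay above all random lists, while collagens (−0.46) lay between the limits. Sense fragments of nrde-3 outnumbered those of every other protein-coding gene in the control IP, and 1 gene had more in each mutant IP.

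A hypothesis of each mutant raising siRNAs from 1 subunit's rRNA was tested only after the total libraries had been seen. In susi-2 26S made up 92.8% of 18S and 26S antisense counts in the IP, against 75.7% in the control. This was the same side as in total small RNA (82.8% against 69.4%), a lean towards 26S. It was not a rise of 1 subunit's rRNA alone, since 18S was also higher, 64.5-fold in the IP and 2.62-fold in total small RNA. In the IP 26S rose 269-fold, 5S 303-fold and 5.8S 1164-fold. In susi-3 18S made up 23.3% in the IP against 24.3% in the control. The lean towards 18S in total small RNA (51.6% against 30.6%) was thus not seen in the IP, and the hypothesis did not hold there.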
